A study of Homo sapiens with 2 samples.

How the data were processed

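DNA bound with a TCF4 antibody was sequenced from CAL-27 sphere cells in 1 library, with 1 IgG library as the control. The labels group the samples by antibody. Per the labels' protocols, complexes were isolated with the antibody, libraries were amplified with indexed primers, and DNA was purified with phenol and chloroform. The labels do not name the assay or the fragmentation. Bowtie2 2.3.5.1, SAMtools (no version), MACS2 2.2.7.1 and the build hg38 are named in the submitters' processing notes, which state no settings. Whether the IgG library served as the control of the peak caller is not given in the sources used here, and that library was not analysed here.

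The deposited peak list gives 4 kinds of value. The fold enrichment is a ratio of the fragments at the summit to the caller's local background, as deposited by the authors. The authors' −log10 p and −log10 q values are the caller's p-value and q-value at the summit. The deposited score is 10 times the −log10 q with decimals dropped. The lowest −log10 q lay just past a q of 0.05. These values were used to describe, rank and filter peaks within this list.

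The fold and the p of a peak were solved for the whole number of fragments at its summit and for the background. This used the caller's forms, fold = (fragments + 1) / (background + 1) and a Poisson upper tail. All 26642 peaks were solved within 0.0001 of the −log10 p, and all 500 simulated peaks were recovered. The background had a floor of 0.475 fragments, reached by 2475 peaks (9.29%). Above it, backgrounds rose in steps of 0.00491, the worth of a single fragment end when fragments of 98.1 bp are spread over 10 kb, so they convert to fragments per 10 kb window. The step was fitted on the 19135 backgrounds under 2. Of all 24167 above the floor, 99.8% lay within 0.05 of a whole step and none farther than 0.106 steps. In the 1157 over 10 times the floor, 96.3% lay within 0.05. At the floor a window holds at most 48.4 fragments. The total number of fragments is not given in the sources used here. Peaks rest on few fragments, and intervals cover counting error only.

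Genes came from a RefSeq table for GRCh38, the assembly that hg38 names, with 58957 records on the main chromosomes, 19862 of them protein-coding. The table has no strand, exons or sequence, and no genome was used here. A summit was therefore called at a gene end when it lay within 1 kb of either end of a record, in place of a transcription start site. Exon, intron and UTR classes, E-box and TCF/LEF motif shares and k-mer enrichment were planned and could not be run. Each summit received 1 class in the order protein-coding gene end, other gene end, inside a protein-coding gene, inside another gene, between genes. The background was 100 random placements of the same number of summits per chromosome, leaving out stretches of over 1 Mb without genes. On simulated summits with 20% planted inside the window of gene ends, a total share of 22.5% was expected and 22.5% was found. Simulated summits with none planted gave 1.06 times the random share.

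The 28 gene lists, with 587 entries all found in the table, were fixed before the data were examined, as were the tests, apart from the replacements given here. Each list was compared with 10000 random lists of its size, a permutation of list membership within the bins of genes described next. The planned matching on promoter GC was replaced by 5 bins of protein-coding gene ends within 100 kb and 3 bins of gene length. The p is the two-sided share of random lists as far from their mean, adjusted over 28 lists by Benjamini-Hochberg and called under 0.05. In a simulation of 200 lists of 25 genes drawn at random, 4.5% had p under 0.05. With 4 times the odds for genes with a peak, 88.0% of 200 lists did. Ratios of medians carry 95% intervals from 1000 bootstraps over chromosomes. Shares carry Wilson intervals and densities exact Poisson intervals.

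Genes were named by a rule: the 10 with the strongest peak at an end, and members of each list. Each list gave up to 4 members with the highest fold and up to 2 without a peak at an end, in alphabetical order. All TCF/LEF, E and ID proteins, the 5 strongest peaks away from gene ends, the 5 genes with most summits inside, and the loci of TCF4, TCF7L2 and AXIN2 were named as well, except for some list members that are not reported here. Alternatives were stricter thresholds, other windows and overlaps, other gene assignment and other backgrounds. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.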

Results

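The series mapped genomic DNA recovered with a TCF4 antibody from CAL-27 cells grown as spheres. CAL-27 is an established line from a human tongue squamous cell carcinoma, and sphere culture is commonly used to enrich for stem-like tumour cells. DNA was recovered with a TCF4 antibody in 1 library and with an IgG control antibody in 1 library. The TCF4 library has a list of 26642 peaks on the human genome build hg38, and the IgG library was not analysed here. With 1 library in each group, no value below has a replicate check, and no test compares the antibodies. Peaks that do not depend on the TCF4 antibody were therefore not separated from sites of TCF4 binding. Tests across genes or chromosomes describe this library alone. The name TCF4 is used for 2 genes, the E protein TCF4, which binds E-box sites as a basic helix-loop-helix factor, and TCF7L2, a nuclear partner of beta-catenin in Wnt signalling. The labels do not say which of them the antibody recognises.

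The peaks covered 6.15 Mb. Their median width was 175 bp, with quartiles of 127 and 278 bp. The median of the authors' fold enrichment was 5.13, with quartiles of 4.34 and 6.47 and a highest value of 59.9. The fold and p of each peak give back the number of fragments at its summit. The median was 10 fragments, with quartiles of 7 and 15, and 55.5% of peaks rested on 10 fragments or fewer. A count of 10 has an exact Poisson interval of 4.80 to 18.4, so the height of a typical single peak is imprecise. At a stricter threshold, 10977 peaks had a −log10 q of at least 5 and 4375 had at least 10.

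Peak summits were concentrated at the ends of genes. Within 1 kb of either end of a protein-coding gene record lay 8579 summits, 32.2% of the total (Wilson interval 31.6 to 32.8%). Random placement on the same chromosomes gave 3.10% ± 0.103 (SD over 100 placements), a 10.4-fold difference. The excess was found on 23 of 24 chromosomes. The gene table used holds no strand, so the start and the finish of a gene could not be separated. Ends of other gene records, mainly non-coding RNA and pseudogenes, held 7.17% of summits, 1.69 times the random share. Summits inside protein-coding genes made up 31.6% against 43.4% at random. The space between genes held 22.6% against 36.9%, and the inside of other genes 6.42% against 12.3%.

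The excess fell steeply with distance. Within 100 bp of a protein-coding gene end lay 2869 summits, 32.1 times the random number. The ratio was 12.2 at 200 to 300 bp, 3.77 at 500 to 1000 bp and 1.72 at 1000 to 2000 bp. From 2000 to 5000 bp it was 1.05, and beyond 100 kb it was 0.405. Summits shifted by 20 kb to either side, a background that keeps the neighbourhood of genes, gave a smaller excess of 5.79-fold at gene ends.

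**Figure D1:**
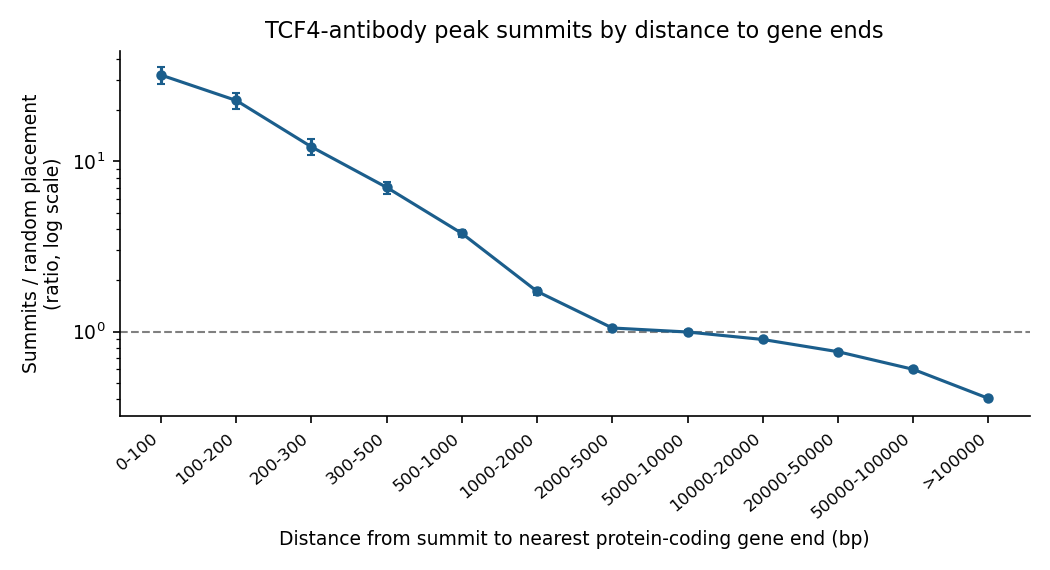
Ratio of observed summits to the mean of 100 random placements (log scale) by distance in bp from the summit to the nearest protein-coding gene end; bars are 1 SD from counting and placement, and the dashed line marks a ratio of 1. The ratio falls from 32.1 within 100 bp to 1.05 at 2000 to 5000 bp and 0.405 beyond 100 kb.

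Peaks at gene ends were also stronger and wider than the others. Their median fold enrichment was 5.81 against 4.87 elsewhere, a ratio of 1.19 (95% interval 1.18 to 1.21 from a bootstrap over chromosomes). Median width was 242 bp against 158 bp, a ratio of 1.53 (1.5 to 1.57). Median fragments at the summit were 12 against 9, a ratio of 1.33 (1.22 to 1.44). All 3 measures were higher at gene ends on 23 of 23 chromosomes with such peaks. The caller's local background was higher at gene ends as well, with a median of 1.09 fragments against 0.898. That ratio was 1.21 (1.16 to 1.29), and the direction held on 21 of 23 chromosomes. The share of summits at gene ends rose with depth, from 18.1% among peaks of 5 to 7 fragments to 46.6% at 16 to 30 and 49.6% at 31 to 60, and was 45.0% over 60 fragments (Wilson interval 39.5 to 50.7%). It was 50.6% in the 500 peaks with the highest fold and 20% in the highest 100. Of the 50 with the highest fold, 4 lay at a protein-coding gene end (8.0%, Wilson interval 3.15 to 18.8%) and 68.0% lay between genes.

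The 10 protein-coding genes with the strongest peak at an end were TAF11L3, NAPA, FXR2, CCDC200, CCM2, ARL6IP1, PC, ISCA2, NPC2 and BRD3OS. The peak beside TAF11L3, on chromosome 5 from 17517617 to 17517869, had a fold of 25.8 on 37 fragments. TAF11L3 belongs to a family of similar copies, and counting can split reads between copies, so its value is uncertain. NAPA, an adaptor in membrane fusion, had a fold of 24.5 on 110 fragments, on chromosome 19 from 47515048 to 47515498. FXR2, an RNA-binding protein, had a fold of 23.9 on 98 fragments, on chromosome 17 from 7614859 to 7615380. CCM2, a scaffold protein of vascular integrity, had a fold of 20.9 on 108 fragments, and PC, the mitochondrial pyruvate carboxylase, had 20.3 on 105. ISCA2 and NPC2 share 1 peak between them, with a fold of 20.3.

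The 5 strongest peaks away from protein-coding gene ends exceeded all of these. The highest was a peak on chromosome Y from 11721926 to 11722134, with a fold of 59.9 on 318 fragments. A peak on chromosome 21 from 7926107 to 7926679 had a fold of 54.5 on 490 fragments. A pair on chromosome 17, from 43251634 to 43251886 and from 43246415 to 43246831, had folds of 46.8 and 43.5. Their summits lay 121 and 785 bp from small nuclear RNA records. They lay 20439 and 15380 bp from CCDC200, whose own peak is among the strongest at gene ends. Whether repeated sequence underlies the pair and the CCDC200 peak could not be tested without sequence. The fifth lay on chromosome 10 from 38835649 to 38835827, with a fold of 41.2. None of the 5 lay inside a gene record.

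The E protein gene TCF4, on chromosome 18, had no summit inside the gene record or within 1 kb of its ends. TCF7L2, on chromosome 10 from 112950247 to 113167678, had a peak at its low-coordinate end with a fold of 4.46 on 7 fragments. A further 3 summits inside the gene had folds of 4.97, 3.56 and 6.07 on 8, 6 and 9 fragments. AXIN2, a feedback inhibitor that serves as a common readout of Wnt signalling, had no summit in the gene or at its ends.

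**Figure D2:**
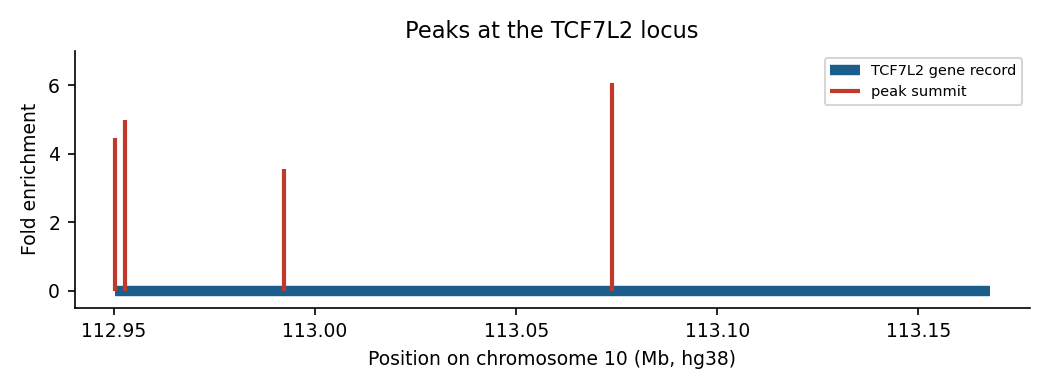
Peak summits at TCF7L2 on chromosome 10 (position in Mb, hg38); the horizontal bar is the gene record and each vertical line is a summit drawn to its fold enrichment. The 4 peaks have folds of 4.46, 4.97, 3.56 and 6.07.

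Of 19862 protein-coding genes, 8240 (41.5%) had a summit within 1 kb of an end. Whether any functional group stood apart was tested with 28 gene lists against 10000 random lists matched for gene length and local gene density, a permutation of list membership among genes of like length and density. After Benjamini-Hochberg adjustment over the 28 lists, 8 had more such genes than matched lists and 2 had fewer. The lists were not matched for promoter GC or for gene activity, so a call cannot be told apart from a difference in either.

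Wnt/beta-catenin target genes and Wnt pathway components did not stand apart in this test. Among Wnt/beta-catenin target genes, 8 of 24 had a summit at an end against 8.47 in matched lists (adjusted permutation p = 1). They included RNF43 and ZNRF3, ubiquitin ligases that remove Wnt receptors, with folds of 10.7 and 9.27. KREMEN1 had a fold of 9.27 and EPHB3 a fold of 6.48, while AXIN2 and BAMBI had no peak. Among Wnt pathway components, 14 of 34 had one against 13.9 (adjusted permutation p = 1). Members of the destruction complex that controls beta-catenin led this list. AXIN1 had a fold of 13.9 on 88 fragments, CSNK1A1 11.5 on 25, GSK3B 10.4 on 43 and GSK3A 6.95 on 22. BCL9 and BCL9L, coactivators of beta-catenin, had no summit at an end. In the TCF/LEF family, TCF7L1 (fold 4.87) and TCF7L2 (4.46) had a peak at an end. LEF1 and TCF7 had no summit at an end, with 2 inside TCF7. The count was 2 of 4 against 1.71 (adjusted permutation p = 1). The central range of its matched lists ran from 0 to 4 genes, every possible count, so this test could not set the family apart. With a −log10 q of at least 5 neither peak remained (3.54 and 2.68). The family then lay below its matched lists (-26.1 percentage points), uncalled, and 4 genes are too few to read this as a depletion.

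The E proteins and their ID inhibitors had a peak in 4 of 7 genes against 2.16 in matched lists (adjusted permutation p = 0.313). ID1 had a fold of 7.99 on 20 fragments, ID3 5.72 on 16, TCF3 4.93 on 18 and TCF12 4.43 on 6. TCF4, ID2 and ID4 had no summit at an end. Class II partners of E proteins had a peak in 3 of 22 genes against 6.26 (adjusted permutation p = 0.257): OLIG2 with a fold of 5.75, TWIST1 with 4.27 and ASCL2 with 4.03. ATOH1 had none. This list was called lower without matching (adjusted permutation p = 0.0183), by Fisher's exact test (adjusted exact p = 0.0207) and with lists from the same chromosomes (adjusted permutation p = 0.0306).

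Genes of the cell cycle and of basic cell functions carried peaks more often than matched lists in the main test. For G1/S and DNA replication the count was 20 of 25 against 10.7 (adjusted permutation p = 0.000933). CHAF1A, a histone chaperone of replicating DNA, had a fold of 13.6, the sliding clamp PCNA 12.7, and the helicase subunits MCM4 and MCM7 12.6 and 9.88. CCNE1 and CDT1 had no peak. For G2/M and mitosis it was 17 of 20 against 8.59 (adjusted permutation p = 0.000933), led by UBE2C (10.9), NUSAP1 (10.9), TTK (8.92) and CDC20 (7.96), with none at BUB1 and CENPE. DNA repair had 21 of 25 against 11.9 (adjusted permutation p = 0.000933), led by FANCA (12.4), ATM (12.2), XRCC6 (11.5) and XRCC1 (10.7). FANCD2 and MRE11 had no summit at an end, with 2 inside MRE11. Cytoplasmic ribosomal proteins had 26 of 33 against 11.9 (adjusted permutation p = 0.000933), with RPL4 at 11.4 and RPLP0 at 10.6. Proteasome subunits had 21 of 26 against 11.2 (adjusted permutation p = 0.000933), with PSMC4 at 14.6 and PSMD2 at 14.4. Each of these 5 calls ended in some of the 15 other settings: 5 for DNA repair, 5 for G2/M, 3 for G1/S, 3 for proteasome subunits and 2 for ribosomal proteins. With the nearest gene end at any distance, DNA repair fell from 36.3 percentage points above its matched lists to 6.35 (adjusted permutation p = 0.621) and G2/M from 42.1 to 24.0 (adjusted permutation p = 0.0835). At high-coordinate ends, G2/M stood at 2.19, G1/S at 9.19 and proteasome subunits at 11.4, all uncalled.

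A further 3 lists lay above their matched lists. AP-1 and immediate early genes, which switch on within minutes of a stimulus, had a peak in 16 of 20 against 7.01 (adjusted permutation p = 0.000933). JUND had a fold of 8.83, JUN 8.12, FOSL2 7.5 and FOSL1 7.41 on 86 fragments, and ATF3 and EGR2 had no summit at an end. This call ended (adjusted permutation p = 0.798) when peaks in the densest 10 kb windows of fragments were left out. Hypoxia and glycolysis genes had 17 of 23 against 9.48 (adjusted permutation p = 0.00448), led by PGAM1 (12.2), P4HA1 (9.01), PDK1 (8.88) and BNIP3 (8.52). ALDOA and CA9 had no summit at an end, with 2 inside ALDOA and 1 inside CA9. MHC class I presentation had 14 of 16 against 6.63 (adjusted permutation p = 0.0016). TAP1 and PSMB8 share a peak with a fold of 11.4, TAP2 had 8.79 and CALR 8.79. ERAP2 and PSMB10 had no summit at an end, with 1 inside PSMB10. The hypoxia call ended in 3 of the 15 settings and the MHC class I call in 1.

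Lists of the squamous and stem-like programmes were not called. Basal squamous epithelium had a peak in 12 of 20 genes against 7.80 (adjusted permutation p = 0.122). LAMB3, a laminin chain that helps anchor basal cells, had a fold of 6.10 on 55 fragments. The basal keratin KRT5 had 6.20 on 53 fragments, 909 bp from its low-coordinate end, and the integrin ITGA6 had 6.44. BNC1 and COL17A1 had no summit at an end, with 4 inside COL17A1. Squamous differentiation had 5 of 26 against 10.9 (adjusted permutation p = 0.0525), including CNFN (8.06), ANXA1 (7.21), S100A8 (4.55) and GRHL3 (3.85), with none at CRNN and CSTA. This list was called lower with windows of 500 bp and 2000 bp, with any overlap of the peak, and with lists from the same chromosomes. The basal list was called higher in 4 settings, among them peaks with a −log10 q of at least 5 (adjusted permutation p = 0.0262). It turned to below its matched lists, uncalled, without peaks in the densest windows (-2.30 percentage points) and in the strongest 25% of peaks (-12.1). Stemness and cancer stem cell genes had 5 of 24 against 8.71 (adjusted permutation p = 0.237), among them EPCAM (9.27), EZH2 (5.74) and POU5F1 (4.19), with none at ABCG2 and ALDH1A1. Epithelial-mesenchymal transition genes had 7 of 25 against 9.60 (adjusted permutation p = 0.388), with ESRP1 at 7.17, CDH1 at 5.58 and TGFBR2 at 5.42. CDH2 and FN1 had no summit at an end, with 1 inside FN1. With the nearest gene end at any distance this list turned from -10.4 to 20.8 percentage points (adjusted permutation p = 0.0835).

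Signalling and drug response lists were not called in the main test. The Notch pathway had 13 of 25 against 9.88 (adjusted permutation p = 0.314), with ADAM10 at 11.8, NOTCH4 at 11.8 and ADAM17 at 8.59. The NOTCH4 summit lay 925 bp from its low-coordinate end, against 178 bp for ADAM10 and 4 bp for ADAM17 at high-coordinate ends. Without strand, it could not be placed at the start or the finish of NOTCH4. The Notch list was called higher with at least 20 fragments at the summit (adjusted permutation p = 0.0409) and with the nearest gene end at any distance (adjusted permutation p = 0.0348). Without peaks in the densest windows it lay 2.18 percentage points below its matched lists (-2.18), uncalled. YAP/TEAD genes had 10 of 22 against 8.37 (adjusted permutation p = 0.59), with F3 at 9.25, YAP1 at 7.14 and TEAD1 at 7.11. TGF-beta/BMP genes had 10 of 20 against 7.75 (adjusted permutation p = 0.428), with SKI at 11.7 and BMPR2 at 8.80. Hedgehog genes had 4 of 15 against 6.03 (adjusted permutation p = 0.388), with SUFU at 11.3, and turned from -13.5 to 25.1 percentage points with the nearest gene end at any distance (adjusted permutation p = 0.118). Drug transport and detoxification had 8 of 21 against 9.38 (adjusted permutation p = 0.733), with NQO1 at 13.3. ABCB1 and ABCC1 had no summit at an end and 1 each inside the gene.

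Markers of other cell types lay below their matched lists, with 2 of the 6 lists called. Hepatocyte markers had a peak in 1 of 22 genes, TF, against 8.23 (adjusted permutation p = 0.0028). Lymphocyte markers had 1 of 20, CD8A, against 8.79 (adjusted permutation p = 0.0021). These calls ended in 5 and 4 of the 15 settings. The peaks at TF and CD8A rested on 6 fragments each and had a −log10 q of 2.35 and 2.48. At a −log10 q of at least 5, without these peaks, both lists stayed called lower (-24.6 and -29.8 percentage points). At 10 they still lay below (-12.4 and -16.2), uncalled. So few genes carried a peak there that a low count could hardly be called, so the lost calls do not show a weaker depletion. Fibroblast and matrix markers had 2 of 17 against 6.57 (adjusted permutation p = 0.0525), ACTA2 and PDGFRB. Endothelial markers had 2 of 15 against 6.15 (adjusted permutation p = 0.0635), SOX17 and KDR. Cardiac muscle markers had 3 of 16 against 6.93 (adjusted permutation p = 0.13), among them RYR2 and MYL7. Neuron markers had 5 of 20 against 7.81 (adjusted permutation p = 0.361), with SYP at 6.70 and GRIN2B at 6.30. With a window of 500 bp, the fibroblast, cardiac and endothelial lists were called lower as well (adjusted permutation p = 0.0366, 0.0165 and 0.0474). The fibroblast list was called lower in 4 settings in all, the cardiac list in 3 and the endothelial list in 1. With the 4375 peaks of −log10 q of at least 10, 3 of the 10 list calls remained: AP-1 and immediate early genes, MHC class I presentation and cytoplasmic ribosomal proteins. With at least 20 fragments at the summit, G2/M and mitosis was no longer above its matched lists (-1.77 percentage points).

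**Figure D3:**
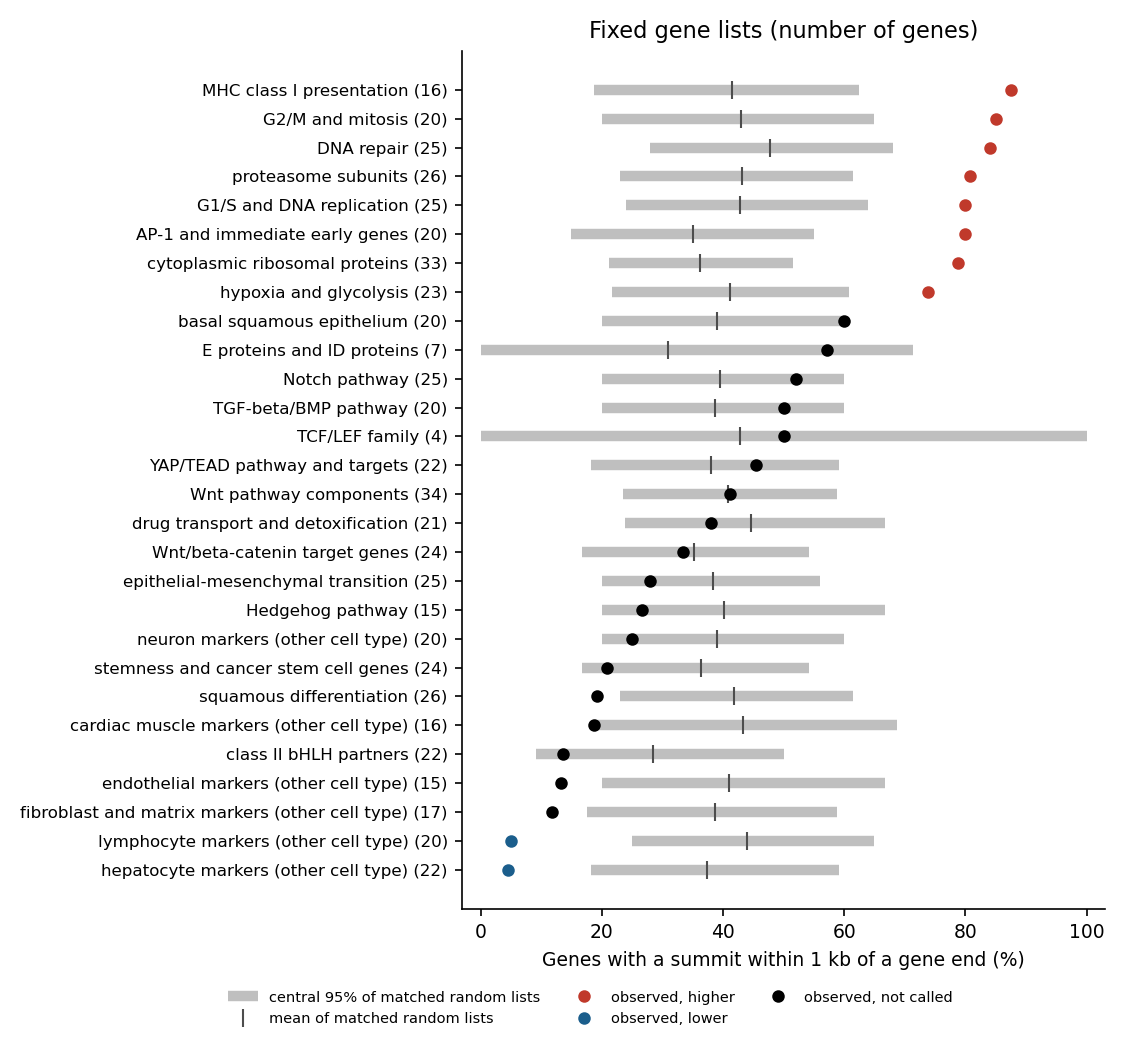
Percent of genes in each list with a summit within 1 kb of a gene end (points; red higher, blue lower, black not called), with the mean (tick) and the central 95% (grey bar) of 10000 matched random lists; the number of genes stands in brackets. The 8 lists called higher lie between 73.9 and 87.5%, and hepatocyte and lymphocyte markers at 4.55 and 5.0%.

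Summits were spread unevenly over the chromosomes. Leaving out chromosome Y, density ran from 29.8 summits per Mb on chromosome 19 (Poisson interval 28.4 to 31.3) to 1.62 on chromosome X (1.43 to 1.84), an 18.3-fold range. It followed gene density across 23 chromosomes, with Pearson's r of 0.910 and Spearman's rho of 0.881 (permutation p = 1e-05 for both, the smallest possible, and 2.0e-05 after adjustment over 4 tests of 2 relations). Without chromosomes 17 and 19, r was 0.813. Per protein-coding gene, chromosome 7 had 2.28 summits (2.19 to 2.38) and chromosome 9 had 2.10 (2.00 to 2.2), against a median of 1.40. Chromosome 4 had 0.646 (0.590 to 0.706) and chromosome X 0.289 (0.254 to 0.327). The genes with the most summits inside them were SDK1 with 29, PTPRN2 with 23, DLG2 with 20, ABTB2 with 17 and MAD1L1 with 17. These counts also follow gene length, and per 100 kb of gene they were 2.997, 2.19, 0.920, 8.21 and 4.08. SDK1, PTPRN2 and MAD1L1 all lie on chromosome 7, which is split at its longest gene-free stretch below. SDK1 and MAD1L1 lie on its lower-coordinate part, with 4.73 summits per gene, and PTPRN2 on its upper part, with 1.13.

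**Figure D4:**
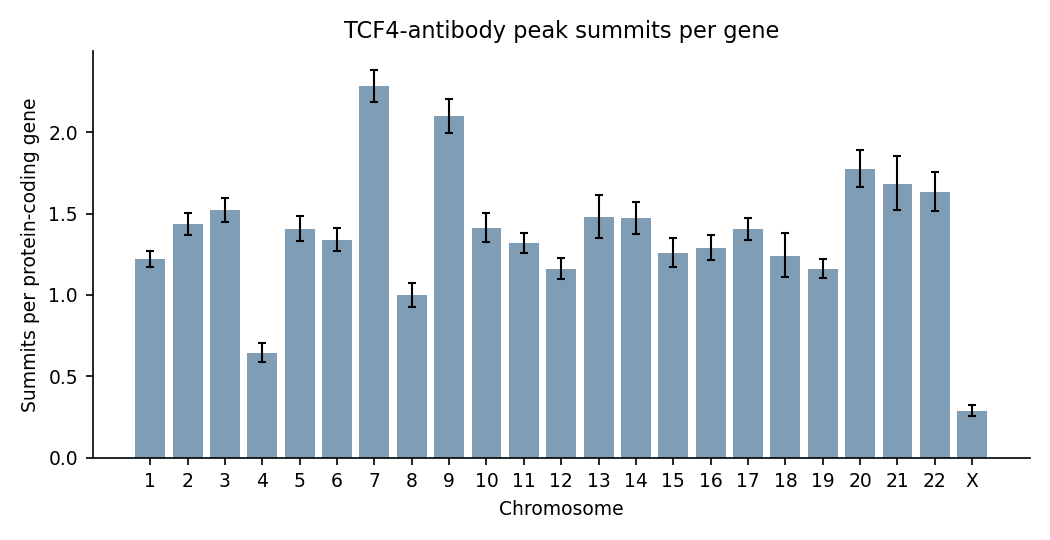
Summits per protein-coding gene on each chromosome, Y left out, with exact 95% Poisson intervals as bars. Chromosomes 7 (2.28) and 9 (2.10) are the highest, and 4 (0.646) and X (0.289) the lowest.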

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

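No paired analysis was possible because each group has 1 library and the result comes from 1 peak list. The settings by fragments, dense windows, single gene ends, shifted summits, gene-free stretches and same-chromosome lists were chosen after seeing the data. Repeat masking, GC matching, 1 start site per gene, and the motif and k-mer settings were not run, for lack of sequence and strand. The number of peaks stayed at 26642 when shared coordinates were counted once. The share of summits at gene ends, 32.2%, was 44.8% at a −log10 q of at least 5, 54.1% at 10, 51.1% in the strongest 25% and 48.2% with at least 20 fragments. It was 26.5% within 500 bp, 37.0% within 2000 bp, 33.0% with any overlap, 19.1% at low-coordinate ends and 18.8% at high-coordinate ends, where the window itself grows or shrinks. The excess over background, 10.4, was 5.79 against shifted summits. The share between genes, 22.6%, was 17.4%, 14.7%, 15.9% and 15.9% in the same 4 subsets of peaks. Peaks at gene ends stayed stronger in all 8 settings tried, with ratios from 1.04 to 1.25. The highest density over the lowest, 18.3, was 22.5 at a −log10 q of 10, 14.4 in the strongest 25% and 49.6 (chromosome 19 over 13) with 20 fragments. The cause was not tested.

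Of the gene lists, 8 were called higher. The number was 3 at a −log10 q of 10, 5 with 20 fragments and 2 at high-coordinate ends, each with fewer genes carrying a peak. With 20 fragments, 3 of the 5 were main calls (AP-1, hypoxia and MHC class I), and basal squamous epithelium and Notch were new. The nearest gene end at any distance gave 8 as well, but lost DNA repair and G2/M and gained the basal and Notch lists. Low-coordinate ends gave 6, losing hypoxia, DNA repair and ribosomal proteins and gaining the basal list. The 2 called lower became 0 at a −log10 q of 10, 0 in the strongest 25%, 0 with 20 fragments, 0 at high-coordinate ends and 1 at low-coordinate ends. Fewer genes carried a peak in the subsets of strong peaks, which left a list little room to lie below its matched lists. The number called lower became 6 within 500 bp, 4 within 2000 bp, 4 without matching, 4 by Fisher's exact test and 5 with lists from the same chromosomes. G2/M and mitosis turned to 1.77 percentage points below its matched lists (-1.77) with 20 fragments. Over 15 settings and the 10 called lists, 118 comparisons held the call, 31 lost it with the same direction and 1 reversed. Of the lists not called, 21 comparisons gained a call, and 10 of these 18 lists changed direction in at least 1 setting. The cause was not tested.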

Other observations

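The tests in this part were chosen after the data were examined. Some peaks stood in 10 kb windows unusually rich in fragments. In 1157 peaks (4.34%) the background was over 10 times its floor, with a median of 716 fragments in the window against 105 over all peaks above the floor. Window counts here and below come from the caller's background, and if its source was the IgG library they describe IgG fragments and not TCF4 fragments. At gene ends these windows marked 357 genes (1.80% of protein-coding genes). The densest held NFKB2 and its neighbour PSD (3021 fragments), the nuclear lamina gene LMNA (2962), the keratin KRT17 (2860.5), the urokinase gene PLAU (2781.5), ACTB (2521) and the immediate early gene ZFP36 (2243.5). The NF-kB inhibitor NFKBIA had 1724. Among the fixed lists, AP-1 and immediate early genes had 8 of 20 members in such windows against 0.529 in matched lists (adjusted permutation p = 0.0028): FOS, FOSB, FOSL1, EGR1, IER3, DUSP1, NR4A1 and ZFP36. Basal squamous epithelium had 5 of 20 against 0.403 (adjusted permutation p = 0.0028), namely KRT5, the neighbours KRT14 and KRT17, ITGB4 and LAMB3. The Notch pathway had 4 of 25 against 0.400 (adjusted permutation p = 0.00467), namely NOTCH1, HES1, NRARP and LFNG. NOTCH1 and NRARP lie on the upper-coordinate part of chromosome 9, HES1 on that of 3 and LFNG on the lower part of 7. These parts, split as described below, had 2.49, 2.44 and 4.73 summits per protein-coding gene, against a median of 1.40 over chromosomes. Matched lists were not matched for chromosome part, so the Notch call cannot be told apart from this regional difference. On chromosome 11, 176 of its 194 peaks in dense windows lay in 1 window of 5 Mb, between 64.0 and 67.6 Mb, where FOSL1 also lies.

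Grouping protein-coding genes by the letters of their symbol gave 146 families of at least 15 members. Of these, 17 had more genes with a summit at an end than matched lists and 27 had fewer. Matched lists draw genes singly from the whole genome. Where the members of a family lie together, the test treats neighbouring genes as independent and overstates the evidence. Genes with the prefix EIF had 43 of 56 against 24.2, INTS 14 of 16 against 7.1, and RAB 44 of 74 against 31.9. These prefixes name translation initiation factors, Integrator subunits and RAB GTPases, but the letters alone also take in other genes that share them. Olfactory receptors (OR) had 5 of 389 against 148.1, keratin-associated proteins (KRTAP) 5 of 94 against 40.5, and beta-defensins (DEFB) 0 of 39 against 15. Collagens (COL) had 3 of 44 against 18.2 and WNT ligands 2 of 19 against 8.17. Zinc finger genes (ZNF) had 177 of 517 against 232.7. Among non-coding records, 16.8% of 429 tRNA genes had a summit within 1 kb against 3.03% for shifted summits. Of the 323 tRNA genes over 5 kb from protein-coding gene ends, 8.67% had one against 1.24%. Pseudogenes not listed as transcribed had 2.5% against 2.62%, while transcribed pseudogenes had 14.7% against 4.16%.

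The backgrounds above the floor rose in even steps of fragments per 10 kb, with 99.8% within 0.05 of a whole step. The hypothesis that they came from the TCF4 library itself predicts that a window never holds fewer fragments than its summit, and the number of such peaks was 0, against 91 to 129 when backgrounds were shuffled over peaks. A background from the IgG library with the caller's default 1 kb window would add backgrounds at multiples of 10 fragments, and these made up 6.16% (Wilson interval 5.86 to 6.47%), against 6.16% for the highest of the other 9 last digits. A first form of this test assumed an even share over all steps and was undecided; it was replaced after its result was seen, because whole fragment numbers made up 58.5% of the steps. The IgG source stays open, since the interval reaches above the highest other digit and the size of the excess it would bring is not known, and no biological explanation was tested.

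Of the 50 strongest peaks by fold, 22 lay within 1 Mb of a stretch of over 1 Mb without genes, against at most 4 in 100 draws of 50 peaks. A hypothesis is that fragments pile up there on repeated sequence around centromeres that the build holds in too few copies, and the count is in line with it. A regional excess of fragments stays open: the median summit held 48.5% of the fragments of its 10 kb window, above the upper quartile of 12.5% over all peaks, but the choice by fold alone requires at least 22.1%. Without sequence, repeats could not be tested directly, and no biological explanation was tested.

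With chromosomes split at their longest gene-free stretch, the lower-coordinate part of chromosome 7 had 4.73 summits per protein-coding gene (4.49 to 4.98) and the upper part of X 0.227 (0.188 to 0.272), so gene number alone does not account for them. Chromosome 3 had 0.481 below and 2.44 above, chromosome 8 had 0.257 and 1.5, and chromosome 18 had 3.29 and 0.540. DNA copy number in this line is a candidate explanation, which predicts richer backgrounds where summits are many. Over 41 parts, the share of isolated peaks of 6 to 8 fragments at the background floor fell with summits per gene (Spearman's rho = -0.628, permutation p = 5.0e-05, the same after adjustment; Pearson's r = -0.652, permutation p = 3.0e-05, adjusted 4.0e-05), and r was -0.773 without the 2 parts farthest from the median. Regional differences in chromatin would give the same relation and were not tested.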
